A study of Arabidopsis thaliana with 6 samples.

How the data were processed

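Total RNA of whole Arabidopsis seedlings was labelled with biotin and hybridised to 1-colour Affymetrix arrays, 3 for mock and 3 for estradiol treatment, per the labels. The seedlings were of the T3 generation, grown in long days of 16 h light and 8 h dark to an age of 14 days, moved to liquid medium overnight, and harvested 2 h after 10 µM estradiol or mock was added. The labels describe the mock as ethanol in one field and as medium without inducer in another, so the vehicle of the mock is not settled here.

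The deposited values are 1 intensity per probe set and array on a linear scale, made by the authors; the tools GCOS and affy are named without version or role per the submitters' processing notes, and the summary method is not given in the sources used here. The 2% trimmed mean was 99.96 on every array, so the arrays had been scaled to a common mean. No detection calls were used here. The share of probe sets with a deposited intensity under the pseudocount of 16 lay between 31.1% and 36% per array. A common scale cannot show a change of total transcript per seedling. The raw signals were not analysed here.

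The table holds 22810 probe sets. The 64 control probe sets were left out, and the 22746 others were tested with no filter. Gene names came from the platform annotation in GEO, updated through Entrez IDs to the TAIR10.1 annotation: 13513 probe sets have 1 gene, 503 have several and 8730 have none listed, which leaves 13355 different named genes. Of the probe sets with 1 gene, 77 have no locus tag and kept the platform's symbol. A gene with several probe sets was represented by the one with the highest mean over all 6 arrays. No coordinates are given because the genome build behind the array annotation is not named.

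Values were transformed as log2(intensity + 16) and compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term) with Benjamini-Hochberg adjustment over all 22746 probe sets; the threshold was an adjusted p under 0.05, and a 2-fold difference was counted besides. Log2 differences are on this scale and understate the change of dim probe sets. Exact permutation of 3 against 3 arrays cannot go below p = 0.1, so all p-values rest on limma's model, which pools the spread over probe sets. The labels call the samples biological replicates.

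The test, the threshold, the rule for named genes, 22 gene lists and the alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and Benjamini-Hochberg adjustment over the lists tested; the 26S proteasome list, as the planned main list, is given with its own p. The minimum of 3 measured members for a list test was chosen after the coverage of the lists was seen and before their results were, and 14 lists reached it. The rule named the target and its relative, up to 12 genes in each direction past the threshold with groups that do not overlap, or the 5 smallest p where fewer than 5 passed, and for each list up to 4 members past the threshold or else the 2 with the smallest p. Probe sets with several genes were not named. Aliases of Arabidopsis genes such as NAS6 are those written with the lists.

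The replicate numbers were not used to pair arrays. The correlation of deviations from the group means of arrays with the same number was 0.091, 0.11 and 0.33, and the first of these is not over 0.1. Alternatives changed the pairing, the scaling between arrays, the filter on dim probe sets, the variance model, array weights, the pseudocount, the list test and the arrays used; 2 sets of arrays were added after the data were seen, one without replicate 3 of both groups and one with mock replicate 3 as the only control.

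The scripts were tested on simulated data. Values were drawn around the real probe set means with the real residual SDs, and 200 of 22746 probe sets were changed in each of 10 runs. The 200 were taken from probe sets with a mean above the median, and the change was added on the log2 scale, so dim probe sets were not covered. At 1 log2 unit limma recovered 55.0% of those lowered and 55.4% of those raised. At 2 log2 units it recovered 91.4% and 93.6%, with 5.5 false calls per run. Simulated genes vary independently, so the list test was checked only for that case: a shift of 0.8 in the 26S list was found in 10 of 10 runs, and 4.3% of unchanged lists had p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.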

Results

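Transcripts were measured on Affymetrix arrays in whole Arabidopsis thaliana seedlings (Col-0 background) that carry an estradiol-inducible construct. In this system the chimeric factor XVE enters the nucleus when estradiol binds it and then drives a transgene from a LexA promoter. The transgene was RPXΔC, a form of the NAC transcription factor RPX that by its name lacks a C-terminal part. RPX is known as a regulator of proteasomal gene expression. Seedlings aged 14 days received 10 µM estradiol or a mock treatment for 2 h, with 3 biological replicates each, so 6 arrays in all. The comparison asks which transcripts differ soon after the inducer is added. No line without the transgene is among the samples, so the effect of RPXΔC and that of estradiol are measured together. The labels do not settle the vehicle of the mock, so an effect of the vehicle may be included as well. The number of arrays limits the precision, and the deposited signals carry no detection calls, so whether a dim probe set lies above background is not known here.

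Median signal was alike on the 6 arrays, between 35.7 and 38.7. Estradiol replicate 3 differed from the rest in the 3'/5' signal ratio of control transcripts, a measure of RNA integrity. Its actin ratio was 15.2, against 4.37 to 6.11 on the other arrays, and its GAPDH ratio was 1.68, against 0.969 to 1.15. Mock replicates 1 and 2 stood apart in another way. Their 25S rRNA control signal was 302 and 286, against 1534 in mock replicate 3 and 918 to 1323 in the estradiol arrays. The first principal component, with 38% of the variance, placed mock replicates 1 and 2 at -26.6 and -24.4, mock replicate 3 at 11.5, and the estradiol arrays at 3.86, 0.417 and 35.3.

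Genes of the proteasome and its assembly made up 5 of the 13 named genes that were higher after estradiol. UMP1A (AT1G67250), a maturation factor of the 20S core, rose from a signal of 514 ± 52.6 in mock to 1452 ± 50.2 with estradiol (mean ± SD, n = 3 each; log2 difference 1.47 ± 0.11 SE, limma adjusted p = 0.0273). NAS6 (AT2G03430), a chaperone of 19S base assembly, rose from 80.6 ± 11 to 319 ± 75.5 (log2 difference 1.77 ± 0.192 SE, adjusted p = 0.0458). RPN2B (AT1G04810), a scaffold subunit of the 19S particle, rose from 169.8 ± 28.5 to 457 ± 34.4 (1.36 ± 0.14 SE, adjusted p = 0.0458), and RPT4B (AT1G45000), an ATPase of the 19S base, from 439.6 ± 28.1 to 926 ± 49.2 (1.05 ± 0.1 SE, adjusted p = 0.045). PBAC2 (AT3G18940), a 20S assembly chaperone, rose by a log2 difference of 0.90 ± 0.101 SE (adjusted p = 0.0493).

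Among the named genes past the threshold, the largest log2 difference was that of GSTU22 (AT1G78340), a tau-class glutathione S-transferase, which rose from a signal of 64.6 ± 14.7 to 512 ± 166 (SD, n = 3; log2 difference 2.67 ± 0.27 SE, limma adjusted p = 0.045). AT3G10590 went from 2.55 ± 0.247 to 43.6 ± 15.6, and its log2 difference of 1.65 understates the change in signal because of the pseudocount of 16. The other named genes that rose were AT1G15920, which encodes a CAF1-type deadenylase (log2 difference 1.29), AT5G51260 (1.21), AT3G47540 (1.199), AT3G18860, which encodes a WD40 protein related to the CDC48 partner PLAA (1.04), and AT3G04780, which encodes a PITH-domain protein (0.98). AT5G03320 (0.79), named after its values were seen, completes the 13. In each of the 13 genes all 3 estradiol values lay above all 3 mock values. The rule for named genes asks for this, so it adds no support.

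Across all 22746 probe sets, 26 were higher after estradiol and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05 in limma, and 23 of the higher ones differed at least 2-fold. Of the 26, 13 belong to a named gene and 13 have no gene listed in the platform annotation used here; among the latter, the probe set with the largest log2 difference (2.28) went from 373 ± 93.9 to 1841 ± 51.5 and the one with the smallest p went from 170.0 ± 24.1 to 802 ± 60.6 (SD, n = 3). Before adjustment, 900 probe sets were higher and 1042 lower at p under 0.05, where chance gives 1137 in both directions together. At an unadjusted p under 0.001 the numbers were 115 higher and 7 lower, where chance gives 23. The number of calls changed with each array left out, which also lowers the power. It was 1 without mock replicate 1, 0 without mock replicate 2 and 2 without mock replicate 3. It was 0 without estradiol replicate 1, 0 without estradiol replicate 2 and 57 without estradiol replicate 3, with 0 lower each time. Of these 57, 21 were among the 26. The differences themselves moved little: the smallest log2 difference among the 26 lay between 0.76 and 0.82 in these fits, against 0.79 with all arrays. The number of calls was also 0 with a pseudocount of 1, and it was 96 when probe sets up to the 25th percentile of mean signal were left out.

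No named gene was lower at the threshold. The 5 with the smallest p in that direction were AT1G26800, which encodes a RING-type ubiquitin ligase (signal 114 ± 6.49 in mock and 69.6 ± 4.37 with estradiol, log2 difference -0.61, limma adjusted p = 0.132), AT4G17250 (-0.82, adjusted p = 0.148), AT5G64880 (-0.77, adjusted p = 0.176), AT3G61930 (-0.65, adjusted p = 0.185) and AT2G39710 (-0.87, adjusted p = 0.208). In each of these the 3 estradiol values lay below the 3 mock values. The genes were picked by the smallest p, so this adds no support. Over all 22746 probe sets, 1761 lay below and 1318 above, where chance gives 1137 in each direction. On simulated arrays with the spread of the real ones, 55.0% of probe sets lowered by 1 log2 unit and 55.4% of those raised by 1 log2 unit were recovered. Each run changed 200 probe sets, against 26 called on the real arrays. The adjusted threshold is easier to reach when more probe sets change, so these rates may be too high here. The changed probe sets were taken from those brighter than the median. These rates therefore do not cover dim genes such as AT4G17250 and AT3G61930, with mean mock signals of 22.2 and 14.1.

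As a group, subunits of the 26S proteasome, the protease that degrades ubiquitin-tagged proteins, were higher after estradiol. Of the 56 listed subunit genes, 9 have a probe set named for them alone, and 8 of these had a positive difference, with a mean log2 difference of 0.79 (SD over genes 0.559; camera p = 2.62e-14; p = 0.0112 with an estimated correlation, or 0.066 when adjusted over the 14 lists tested; fry p = 0.000855). The other listed genes, called not measured here, may lie among the 8730 probe sets with no gene listed or the 503 with several. On all genes 2 of the 9 passed the threshold, and 7 passed when p was adjusted over the list alone. The members beyond RPN2B and RPT4B were named after their values were seen, except PAB2. RPN11, the deubiquitinating subunit of the 19S lid, had a log2 difference of 1.54 (limma adjusted p = 0.0683 over all genes), RPN12A 0.95, PAB2 0.91 (adjusted p = 0.121) and RPN7 0.87. RPN2A had 0.45, RPN3B 0.15 and RPN9A -0.20. PAB2 is the one measured member of the 20S list of 24 genes, so the group speaks mainly for the 19S particle, of which 8 of 32 genes were measured (mean log2 difference 0.77, camera adjusted p = 1.83e-11; adjusted p = 0.066 with an estimated correlation). The calls of RPN2B and RPT4B ended without any 1 of the 3 mock arrays or of estradiol replicates 1 and 2; their log2 differences lay between 1.24 and 1.46 and between 1.00 and 1.09 when each array was left out, and the list's mean between 0.73 and 0.87.

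**Figure D1:**
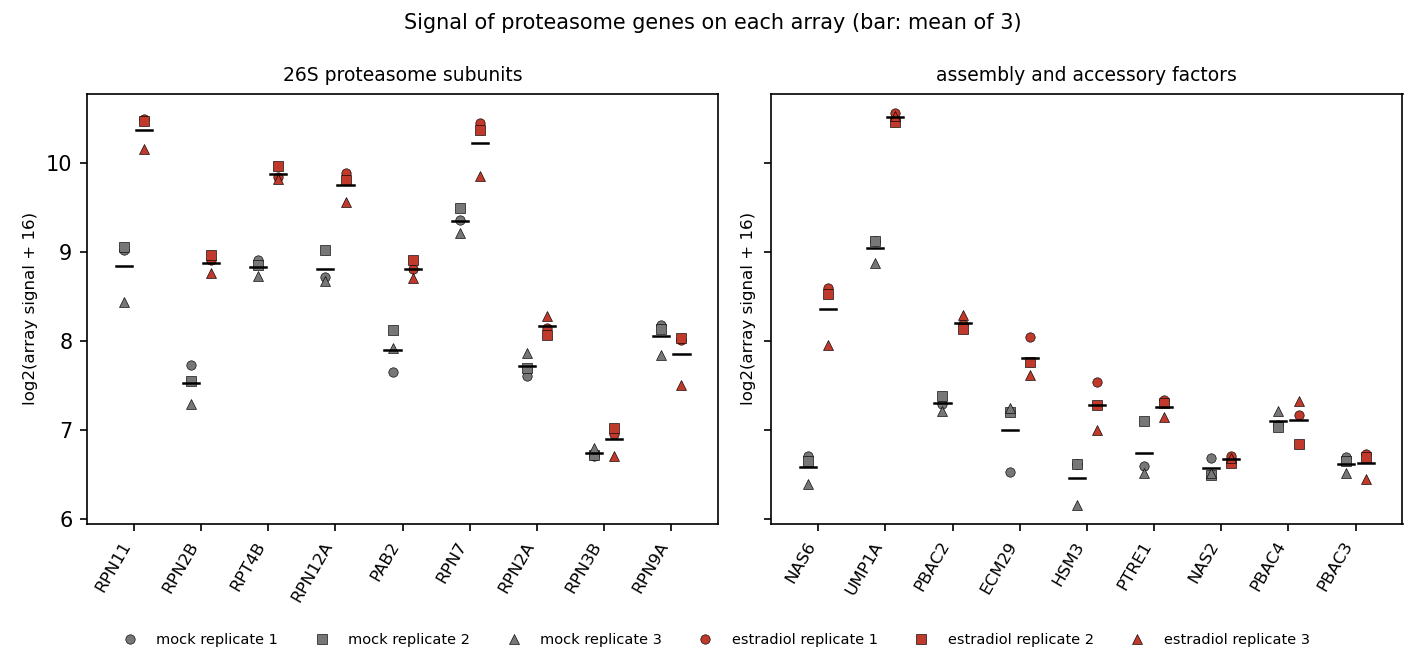
Signal as log2(array signal + 16) on each of the 6 arrays for the 9 measured 26S proteasome subunits (left) and the 9 measured assembly and accessory factors (right); grey symbols are mock, red symbols estradiol, symbol shapes are replicates and bars are means of 3. All 3 estradiol values lie above all 3 mock values in 7 of the 9 subunits and in 6 of the 9 factors, while NAS2, PBAC4 and PBAC3 overlap.

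Assembly chaperones and accessory factors of the proteasome had a positive mean difference as a list, which rests on part of its members. Of 14 listed genes 9 were measured, 3 passed the threshold on all genes (NAS6, UMP1A and PBAC2) and 6 passed when adjusted over the list alone. Their mean log2 difference was 0.71 (SD 0.628; camera adjusted p = 2.24e-10; adjusted p = 0.066 with an estimated correlation; fry adjusted p = 0.00497). ECM29 (0.82), HSM3 (0.81) and PTRE1 (0.53) had positive differences that did not pass on all genes, and NAS2 (0.11), PBAC4 (0.01) and PBAC3 (0.00) lay near 0; these 6 were named after their values were seen. Without any 1 of the mock arrays or of estradiol replicates 1 and 2, 0 of the 9 passed on all genes; the log2 differences when each array was left out were 1.66 to 1.98 for NAS6, 1.39 to 1.52 for UMP1A and 0.86 to 0.95 for PBAC2. The 18 measured genes of both groups had mean log2 signals of 7.62, 7.72 and 7.53 on the mock arrays and 8.47, 8.41 and 8.25 on the estradiol arrays. The lowest of the latter is estradiol replicate 3, which has the raised 3'/5' ratios.

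Genes of xenobiotic detoxification were higher as a list, which rests on glutathione S-transferases. Of 27 listed genes 4 were measured, with a mean log2 difference of 1.54 (SD 1.36; camera adjusted p = 2.88e-05; adjusted p = 0.194 with an estimated correlation). GSTU22 passed on all genes and 3 of the 4 passed when adjusted over the list alone. GSTU25 went from a signal of 40.7 to 358 (log2 difference 2.68, limma adjusted p = 0.121 over all genes). The transporter gene DTX3 had a difference of 0.84 and AER, an alkenal reductase gene, -0.02; these 3 were named after their values were seen. The call of GSTU22 ended without any 1 of the mock arrays or of estradiol replicates 1 and 2, with log2 differences between 2.51 and 2.97 when each array was left out. Estradiol replicate 3, the array with the raised 3'/5' ratios, stood lower on this list: the mean log2 signal of the 4 genes was 8.84, 8.73 and 7.99 on the estradiol arrays and 7.20, 6.75 and 6.99 on the mock arrays. DTX3 gave 61.5 on estradiol replicate 3, below its 73.8 on mock replicate 3.

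Autophagy genes had a small positive shift: of 16 listed genes 10 were measured and 8 had a positive difference, with a mean log2 difference of 0.16 (SD 0.228; camera adjusted p = 0.0301; adjusted p = 0.251 with an estimated correlation; fry adjusted p = 0.207). Apart from ATG3 (-0.01, named after its values were seen), the measured members were all ATG8 genes, so the list speaks mainly for that family. None of the 10 passed limma's threshold on all genes or adjusted over the list alone, and the 2 with the smallest p were ATG8B (0.39, adjusted p = 0.431) and ATG8A (0.41, adjusted p = 0.579), which encode ubiquitin-like proteins of the autophagosome. The list's call ended without mock replicate 1 (adjusted p = 0.123), without estradiol replicate 1 (0.0936), after quantile normalization (0.095), with a pseudocount of 1 (0.0571) and with the filters on dim probe sets (0.053 and 0.0687).

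**Figure D2:**
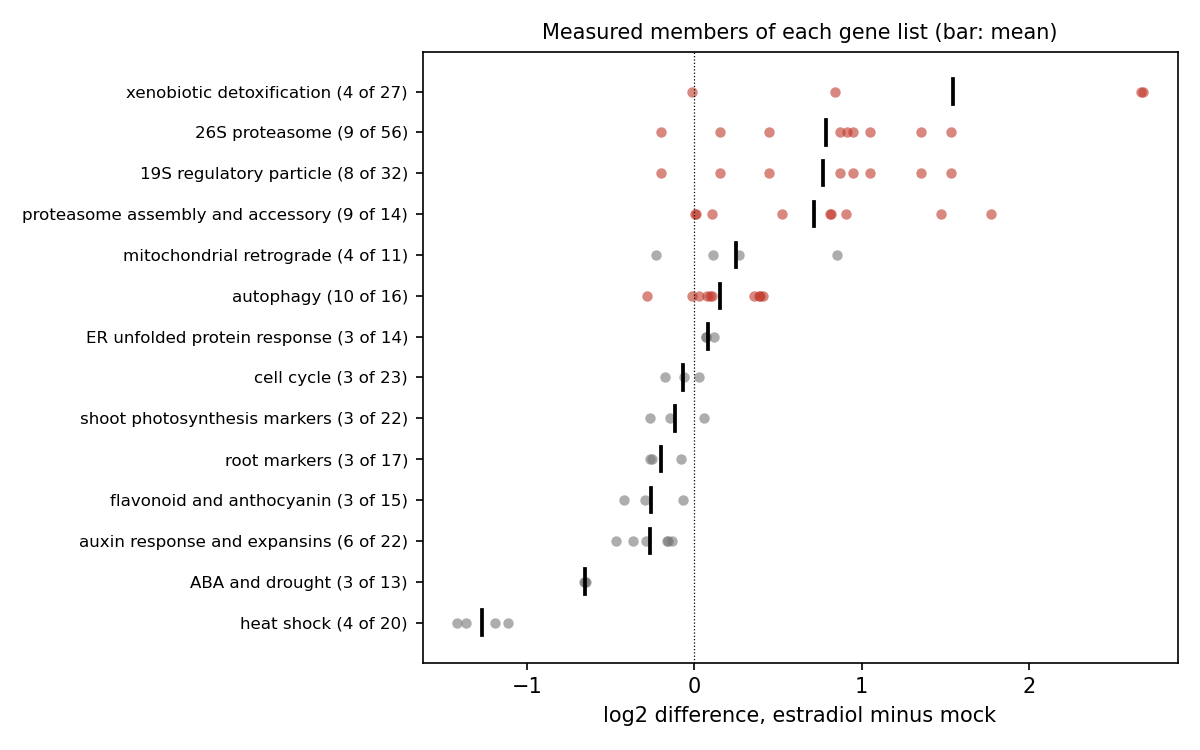
Log2 difference between estradiol and mock (horizontal axis) of each measured member (points) of the 14 gene lists with at least 3 measured members, with the list's mean as a bar and the measured and listed numbers of genes in brackets. Red lists have a camera adjusted p under 0.05 with the preset correlation; their means lie between 0.16 and 1.54.

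Among the remaining lists with at least 3 measured members, none passed camera's threshold after adjustment and none held a gene past limma's threshold; the camera p of the auxin and expansin list, 0.0482 before adjustment, did not hold after it. All 4 measured heat-shock genes had negative differences (mean log2 difference -1.27, camera adjusted p = 0.171), and the mock arrays disagreed on them. HSP22 gave 647, 441 and 18.9 on mock replicates 1, 2 and 3 and 110.0, 118 and 20.8 on the estradiol arrays, and FKBP65 gave 705, 651 and 63.4 against 136, 231 and 69.6. The 3 measured genes of abscisic acid and drought (COR47, LTI30 and COR15A) had a mean of -0.66 (adjusted p = 0.146) with the same split of the mock arrays: LTI30 gave 763, 558 and 327. Replicate 3 was the lowest in both groups. Mean log2 signals of the heat-shock genes were 9.98, 9.71 and 5.94 in mock and 7.82, 8.11 and 5.88 with estradiol. Those of the abscisic acid genes were 9.59, 9.63 and 7.69 in mock and 8.83, 8.49 and 7.63 with estradiol. Both mean differences depended on single arrays. The heat-shock mean was -0.56, -0.69 and -0.58 without mock replicate 1, mock replicate 2 or estradiol replicate 3, and that of the abscisic acid list was -0.34, -0.32 and -0.31. Without mock replicate 3 they were -2.57 and -1.30 and passed at the preset correlation (camera adjusted p = 0.000385 and 0.00181). With an estimated correlation the adjusted p on all arrays was 0.524 and 0.499. Mock replicates 1 and 2, which were high for these genes, are also the arrays with the low 25S rRNA signal.

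**Figure D3:**
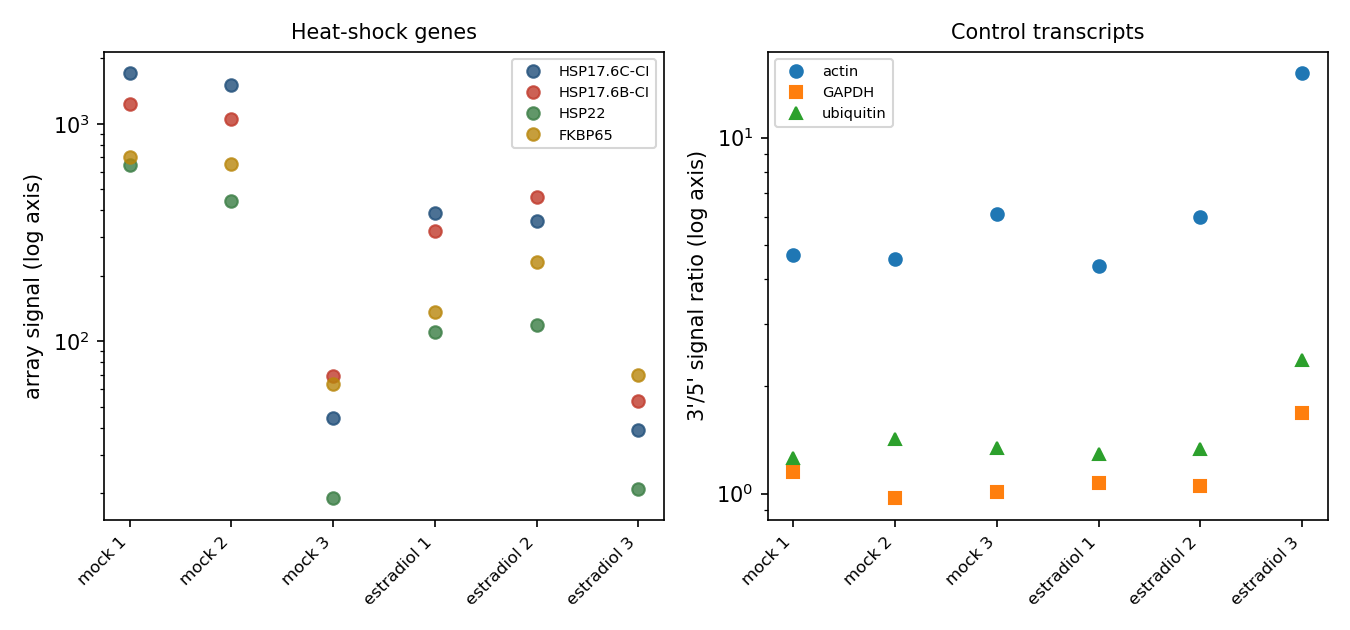
Left, array signal (log axis) of the 4 measured heat-shock genes on each of the 6 arrays; right, 3'/5' signal ratio (log axis) of 3 control transcripts on the same arrays. Mock replicates 1 and 2 have the highest heat-shock signals, for example 647 and 441 for HSP22 against 18.9 in mock replicate 3, and estradiol replicate 3 has the highest ratios, with 15.2 for actin.

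The mitochondrial retrograde list had a mean log2 difference of 0.25 (camera adjusted p = 0.146), with UPOX at 0.85 (limma adjusted p = 0.528) and UNK1 at 0.27. The list of auxin response and expansins had a mean of -0.26 (adjusted p = 0.112), with all 6 measured members negative, IAA29 at -0.29 and EXPA8 at -0.47; its mean was -0.34 without mock replicate 1 (adjusted p = 0.0478), -0.33 without mock replicate 2 (adjusted p = 0.0152) and -0.12 without mock replicate 3 (adjusted p = 0.556). With an estimated correlation the list's adjusted p on all arrays was 0.357. The mean of the auxin and expansin list was -0.50 with a pseudocount of 1 and -0.13 with 64. Flavonoid and anthocyanin genes had a mean of -0.26 (adjusted p = 0.146), with UF3GT at -0.42 and UGT75C1 at -0.30, and the mean was -0.43 without mock replicate 3 (adjusted p = 0.00702) and -0.12 without mock replicate 2 (adjusted p = 0.407). With an estimated correlation this list's adjusted p on all arrays was 0.499. Its 3 measured members were dim. Their group mean signals lay between 1.29 (UGT75C1, estradiol) and 14.4 (UF3GT, mock), all below the pseudocount of the main fit. Whether they lie above background is not known here. The mean of the flavonoid and anthocyanin list was -0.80 with a pseudocount of 1 and -0.09 with 64, so its size depends on that setting. The unfolded protein response of the endoplasmic reticulum (mean 0.08, adjusted p = 0.248), with CRT2 at 0.12 and BZIP60 at 0.07, and the cell cycle list (mean -0.07, adjusted p = 0.783), with AUR2 at -0.17 and AUR1 at -0.06, did not pass. When each array was left out, the former mean ranged from -0.009 to 0.142 and the latter from -0.221 to 0.054, so neither sign held. The tissue markers of the shoot (mean -0.12, adjusted p = 0.302), with LHCB4.3 at -0.27 and LHCB4.2 at -0.15, and of the root (mean -0.20, adjusted p = 0.146), with EXPA18 at -0.26 and PYK10 at -0.27, did not pass either. When each array was left out, the shoot mean ranged from -0.175 to -0.035 and the root mean from -0.302 to -0.115. Against mock replicate 3 alone they were -0.281 and -0.356.

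Lists with fewer than 3 measured members were not tested as lists. Their measured genes, named by the smallest p, were UBC28 of ubiquitin and conjugation (-0.33), CSN5B of the COP9 signalosome (-0.17), EIF3D of eIF3 (-0.01), GI of the circadian clock (-0.33), FAMA of guard cell and phloem markers (-0.12), and WRKY53 (0.16) and ZAT10 (0.20) of the wound, touch and jasmonate list. None passed limma's threshold. When each array was left out, UBC28, CSN5B and GI stayed negative, but the signs of the others did not hold. EIF3D ranged from -0.228 to 0.176, FAMA from -0.249 to 0.092, WRKY53 from -0.018 to 0.307 and ZAT10 from -0.101 to 0.607. No member of the reactive oxygen list has a probe set named for it alone. RPX, taken here as ANAC078 (AT5G04410), and its closest relative ANAC053 (AT3G10500) have no probe set listed in the annotation used, so the induction of the transgene itself was not analysed here.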

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

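The tests in this part were chosen after the values were seen, except the splits of the arrays for the lists. Single arrays were not tested as outliers within the groups of 3. Of the 64 control probe sets, which enter no comparison, AFFX-Athal-GAPDH_M_s_at was above every mock array after estradiol by a log2 difference of 0.289 (mean signal 1326 in mock and 1625 with estradiol). Another probe set of that transcript, AFFX-Athal-GAPDH_3_s_at, overlapped at -0.038. AFFX-r2-At-Actin-M_s_at was below every mock array by -0.283 (974 in mock and 799 with estradiol). Of the 64, 2 lay above all mock arrays and 5 below, where chance gives 1 in 20 for each direction.

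If the RNA quality of estradiol replicate 3 had made the rise of proteasome subunits and assembly factors, the other estradiol arrays would not exceed mock, but the lower of estradiol replicates 1 and 2 exceeded the highest mock array by 0.686 in the mean log2 signal of the 18 genes, against a largest SD of 0.114 within a group. If the state shared by mock replicates 1 and 2 had made it, mock replicate 3 would be as high as the estradiol arrays, but the lowest estradiol array exceeded it by 0.72. What stays open is whether estradiol alone, or a vehicle that the mock may have lacked, raised these genes. No line without the transgene is present. The detoxification list, which holds genes that respond to foreign chemicals, had a mean difference of 1.544. Without such a line this rise too may come from estradiol or from RPXΔC, so it favours neither. That list passed with the preset correlation but not with an estimated one (adjusted p = 0.194), and its mean rests on GSTU25 and GSTU22 among 4 genes, with AER at -0.02. The biological explanation, induction by RPXΔC, cannot be told apart from an effect of estradiol or its vehicle with these samples.

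The heat-shock genes were high in mock replicates 1 and 2 and low in mock replicate 3, and among the estradiol arrays replicate 3 was also the lowest. The treatment cannot be the whole cause, since the lower of mock replicates 1 and 2 exceeded mock replicate 3 by 3.773 in the mean log2 signal of the 4 genes (SD of the estradiol arrays 1.22). Within replicates 1 and 2 mock exceeded estradiol by at least 1.601. No replicate number has a repeat array within a group, so the spread between arrays of one day is unknown. Whether a day shared by arrays of one replicate number is the whole cause therefore cannot be decided. A combination of the treatment with differences between days or plates may account for both differences and was not tested.

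The 6 arrays can be split in 10 ways, too few for a share under 0.05. The real split gave 26 probe sets past the threshold and 23 of them at least 2-fold, and the highest other split gave 0 for both. It gave a mean shift of the 26S list of 0.785, against 0.435 for the highest other split; for each of these 1 split, the real one, reached the value. For lists other than the 26S list it gave 4 past the threshold, while the highest other split gave 5 and 4 of the 10 splits gave at least 4, so the number of lists carries no weight here. The split of mock replicates 1 and 2 with estradiol replicate 2 against the rest gave 1989 probe sets with an unadjusted p under 0.05, against 1942 for the real split.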

How the results depend on the processing

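The 26S proteasome list passed, at its own p, under each alternative run, with means from 0.71 to 0.896 (adjusted over the lists, it missed with an estimated correlation, p = 0.066). The numbers of calls did not hold. From 26 higher, they went to 43 with arrays centred on the median, 51 with an intensity trend and robust variances, 91 with array weights, 96 and 87 with the filters at the 25th percentile and the median, 11 with a pseudocount of 64 and 0 with a pseudocount of 1. At least 2-fold, from 23, they went to 38, 45, 71, 77, 63, 5 and 0 in that order. From 0 lower, both filters gave 1 (also 1 at least 2-fold) and array weights gave 1. Leaving out each array in turn gave 0 to 57 higher, 0 to 55 of them at least 2-fold. The cause was not tested for any of these settings. A low pseudocount gives weight to dim signals, whose level over background is unknown here.

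With the replicate number as a block, 17 probe sets were higher, 6 of them among the 26. Of the 13 named genes past the threshold, NAS6 and UMP1A passed with the block and the others, RPN2B, RPT4B, PBAC2 and GSTU22 included, did not, while RPN11 and GSTU25 came to pass. With it 2 other lists became lower (heat shock and abscisic acid) and the mitochondrial retrograde list became higher (adjusted p = 0.0416), all at the preset correlation; without the block, these 3 lists had an adjusted p of 0.524, 0.499 and 0.357 with an estimated one. Arrays with the same number did not deviate together in every pair (r of 0.091, 0.11 and 0.33), and only the arrays of replicate 3 correlated best with each other.

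With 2 sets of arrays chosen after seeing the data, the counts were 0 higher, and 0 at least 2-fold, both with only replicates 1 and 2 and with mock replicate 3 as the only control, which is assumed to vary like the estradiol arrays; fewer arrays lower the power. With only replicates 1 and 2, 3 lists became lower: heat shock, flavonoid and anthocyanin, and abscisic acid. Other lists moved down against mock replicate 3 alone, with means of -0.552 for auxin and expansins, -0.356 for root and -0.281 for shoot markers. There the unfolded protein response mean was 0.269, and the heat-shock list reversed to 1.332. From 0 lists lower, leaving out 1 array gave 0 to 3, and the filter at the median 1. With an estimated correlation, 0 of the 4 other lists that were higher passed.

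Of the values of single genes, 1048 stayed on their side of the threshold, 252 were no longer past it and 18 came to pass it. Of those of lists, 239 stayed, 12 lost and 16 gained the call in the same direction, and 1, given above, reversed. Those that stayed include genes and lists that did not pass in the main fit, so these numbers do not measure how well calls held. Of the 26 called probe sets, 26 still passed with arrays centred on the median, 19 after quantile normalization, 6 with the replicate block and 0 with a pseudocount of 1. No alternative could be run for the induced transgene, which has no probe set listed.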

Other observations

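The tests in this part were chosen after the values were seen. At an adjusted p under 0.2 in limma, 122 probe sets were higher, the 26 past the threshold included, and 8 were lower. At an unadjusted p under 0.05 the balance was the other way, with 900 higher and 1042 lower. Among named genes with an adjusted p under 0.1, named after their values were seen, were AT2G20720, from a signal of 7.52 to 91.7 (log2 difference 2.19, adjusted p = 0.0584), AT5G05190 (2.101, adjusted p = 0.0693) and AT5G56350, which encodes a pyruvate kinase (1.29, adjusted p = 0.0655). Differences varied among subunit genes: RPN9A (-0.20) and RPN3B (0.15) differed little in these arrays while RPN11 (1.54) and RPN2B (1.36) differed most; whether such pairs differ from each other was not tested.

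Whether genes that share a regulatory region with a higher gene might rise with it stays open, because the annotation table used gives no strand and divergent pairs are not known. Values are given for the protein-coding genes next to the 24 named genes higher at an adjusted p under 0.1, in any orientation. Of 25 measured neighbours 9 had a positive difference, and their mean log2 difference of -0.039 was not above that of neighbours of random genes (one-sided permutation p = 0.617 from 10000 draws). With neighbours of any gene type, tried first, the mean of 15 was -0.091 (permutation p = 0.905). One protein-coding neighbour stood apart, AT1G23830 at a log2 difference of 1.07 (limma adjusted p = 0.105), next to AT1G23840 at 0.95 (adjusted p = 0.0972).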
